A study of Bos taurus with 5 samples.

How the data were processed

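RNA from pools of 100 bovine embryos was extracted with a column kit for small samples and made into libraries with a stranded mRNA kit, per the labels' protocols. The labels give 3 pools to the high-performing and 2 to the low-performing sire group and do not define performance. The treatment protocol names recombinant Wnt5A for all 5 samples alike, with no dose, so it forms no group here. Per the submitters' processing notes, FastQC, featureCounts and edgeR were used with the cattle genome build ARS-UCD1.2; the aligner, the versions and the strand setting of the counting are not given in the sources used here.

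The deposited table holds 27607 Ensembl genes with their position and length, and RPKM per library computed by the authors. RPKM is reads per kilobase of gene, scaled to a fixed total of reads counted in genes. In every library the deposited RPKM times length in kilobases summed to 1000000, so no trimmed-mean factor had been applied. All RPKM values came out as whole reads within a tolerance of 1e-06, which gave the depths in the report. The authors also deposited log2 fold changes and mean log2 CPM, a likelihood ratio score per gene, and p-values with an FDR, which equalled the Benjamini-Hochberg adjustment of the p-values; the model formula and the dispersion method are not given in the sources used here. The sign of the authors' log2 fold change is positive where the low-performing pools are higher. Gene names came from the file, which names 19766 genes and leaves 7841 without a symbol; 0 of the Ensembl identifiers matched the RefSeq table (assembly ARS-UCD2.0), and 2 unnamed mitochondrial genes were taken as the rRNAs because their lengths, 955 and 1571 bases, are those of its mitochondrial rRNA genes. No column of per-sample values was left unmapped.

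Choices made before the data were examined were the main test, its filter, the gene lists, the rule for named genes and most alternatives. The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(RPKM + 1) for genes with an RPKM of at least 1 in at least 2 of the 5 libraries, 12448 genes in all, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. A pseudocount of 1 understates the change of genes with low values. For 25 gene lists of oocyte and cleavage-stage biology and of other cell types (cumulus and granulosa, sperm, blood), 1265 of 1339 symbols were matched, and the 24 lists with at least 5 tested members entered limma camera with a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation and fry. The level of a list in a pool is the mean log2(RPKM + 1) of its tested members.

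Genes were named by rule. The first part took 10 genes per direction past the threshold by size of change, or, where too few passed, those with the smallest p whose libraries did not overlap between groups. The second took up to 4 members of each list past the threshold, or else the 1 member with the smallest p, and the third a fixed set of genes, of which KDM4E was not matched and 1 is not reported here. Other members named beside their list were chosen after their values were seen.

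Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean RPKM of 5, quantile normalization, a trimmed-mean factor on RPKM, limma without trend, with a robust prior or with library weights, the replicate number as a block, a threshold of 0.1, a minimum log2 fold change of 1, and each library left out. Removal of a loess trend of each library over log2 gene length (span 0.5) and limma voom on the recovered reads were added after seeing the data, as were the histone, small nuclear ribonucleoprotein (snRNP), LSM, mitochondrial ribosome and structural RNA groups of the closing section. Principal components and correlations used the 12448 genes.

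The script was tested on simulated reads with the real means and depths and a dispersion of 0.02. For 3 high-performing against 2 low-performing libraries with independent noise and 12380 genes, limma recovered 5.97% of genes changed by 0.5, 87.9% of those changed by 1 and 100% of those changed by 2 on the log2 scale, and called 4 unchanged genes. The simulation had 1 dispersion for every gene and no pool differences shared across genes, unlike the real pools. These rates are therefore not the power of the real comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.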

Results

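The series compared early cattle embryos (Bos taurus) developed in vitro and sired by high-performing or by low-performing bulls, to learn how the sire's performance class goes with the embryo's transcriptome. The labels place every embryo at the 4-cell stage, while the series text gives a range of 2 to 4 cells. RNA was sequenced from 5 pools of 100 embryos each, 3 in the high-performing group and 2 in the low-performing group. The reads in genes worked out from the deposited values came to 113100809, 67248924 and 90237317 in high-performing pools 1, 2 and 3, and to 98684834 and 93659589 in low-performing pools 1 and 2. Between 19481 and 20217 genes had a value above 0 in a pool. At these depths 3 reads in a gene of 1 kb correspond to 0.027 to 0.045 RPKM, which covers counting error only. The labels do not say whether pools of a group came from separate sires, fertilisations or cultures, so the p-values measure the spread between these pools, which may be technical. All fold changes are low-performing minus high-performing on the log2(RPKM + 1) scale.

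Messenger RNAs for the cytosolic ribosome were more abundant in the low-performing pools. The 82 ribosomal protein mRNAs tested had a median log2 fold change of 0.90, and all 82 lay above 0. Their mean level was 4.11 ± 0.17 (SD, n = 3) in the high-performing pools and 5.0 ± 0.56 (SD, n = 2) in the low-performing pools, in log2(RPKM + 1). In limma, 67 of the 82 rose when p-values were adjusted over the list alone, and 0 passed over all 12448 genes tested. RPS21, a protein of the small subunit, had 8.38 ± 1.07 RPKM (SD, n = 3) in the high-performing pools and 25.1 ± 11.8 RPKM (SD, n = 2) in the low-performing pools, a log2 fold change of 1.40 ± 0.27 (SE). RPL35A, of the large subunit, had 52.1 ± 19.6 RPKM (SD, n = 3) and 181 ± 86.1 RPKM (SD, n = 2). The libraries of the groups did not overlap for 72 of the 82, always with the low-performing pools higher. Averaged over all splits of the 5 pools into 3 and 2, chance gives 20% of genes in either direction. In the real split 58.7% of all 12448 genes tested did not overlap, 3658 with the low-performing pools higher and 3647 with them lower. As a set the list was higher by limma camera with the preset correlation of 0.01 (adjusted p = 4.15e-20). That call was lost with an estimated correlation (adjusted p = 0.688), and adjusted p ranged from 1.32e-28 to 0.688 over the alternatives. Low-performing pool 2 stood apart in this list, at a level of 5.40 against 4.61 in low-performing pool 1, and the median was 0.49 without pool 2 and 1.30 without pool 1. The members are short, with a median length of 820.5 bases, and with the trend over gene length removed the median was 0.58. Ribosomal protein genes have many near-identical pseudogenes, which makes single members uncertain.

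Nuclear-encoded subunits of the oxidative phosphorylation complexes, which make ATP in mitochondria, were higher in the low-performing pools by a median log2 fold change of 1.11 over 76 mRNAs, of which 75 lay above 0. Of these, 62 rose with p-values adjusted over the list alone in limma, none fell, and 0 passed over all genes. NDUFA12, a complex I subunit on chromosome 5, had 4.12 ± 1.33 RPKM (SD, n = 3) in the high-performing pools and 13.4 ± 4.58 RPKM (SD, n = 2) in the low-performing pools, a log2 fold change of 1.49 ± 0.27 (SE). COX6B1, a complex IV subunit, had 7.98 RPKM and 28.0 RPKM on average, and NDUFAB1, the mitochondrial acyl carrier protein, had 280 and 702 RPKM. The list mean per pool was 4.26 ± 0.22 (SD, n = 3) against 5.25 ± 0.58 (SD, n = 2). limma camera gave an adjusted p of 7.74e-20 with the preset correlation and an adjusted p of 0.688 with an estimated correlation, within a range of 4.30e-35 to 0.688 over the alternatives. The level was 4.84 in low-performing pool 1 and 5.66 in low-performing pool 2, and the median was 0.62 without pool 2. The median length of the members was 1095 bases.

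**Figure D1:**
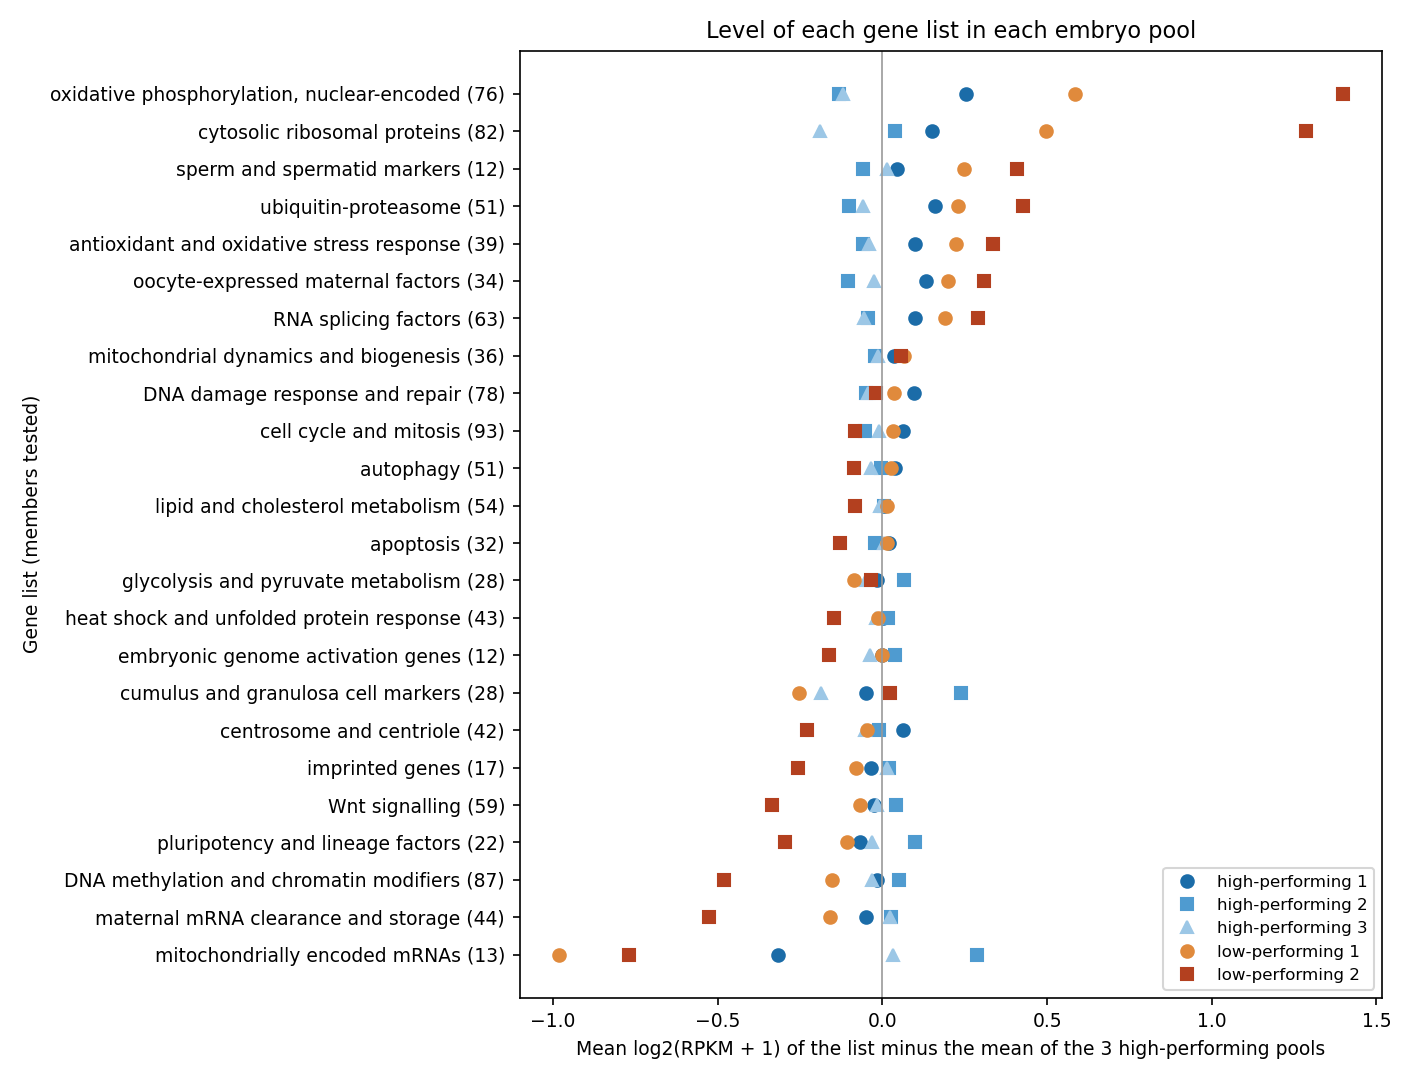
Mean log2(RPKM + 1) over the tested members of each fixed gene list, per embryo pool, minus the mean of the 3 high-performing pools; each point is 1 pool, and the number of members is in parentheses. Oxidative phosphorylation and ribosomal protein mRNAs lie highest in both low-performing pools, and mitochondrially encoded mRNAs lie lowest.

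The mRNAs encoded by the mitochondrial genome itself were lower in the low-performing pools, with a median log2 fold change of -0.69 over 13 mRNAs. In limma 7 of them fell with p-values adjusted over the list alone, and 0 passed over all genes. The 7 were CYTB of complex III and 6 of the 7 complex I subunits, ND1, ND2, ND4, ND4L, ND5 and ND6. ND2 (mitochondrial chromosome, positions 4266 to 5307 of the ARS-UCD1.2 build) had 527 ± 87.6 RPKM (SD, n = 3) in the high-performing pools and 224 ± 18.3 RPKM (SD, n = 2) in the low-performing pools, a log2 fold change of -1.22 ± 0.18 (SE). ND4L had 964 ± 315 RPKM (SD, n = 3) and 241 ± 112 RPKM (SD, n = 2), and ND5 had 451 ± 137 RPKM (SD, n = 3) and 123 ± 46.8 RPKM (SD, n = 2). COX3, of complex IV, had 1239 ± 47.7 RPKM (SD, n = 3) and 1999 ± 1311 RPKM (SD, n = 2), with 1072 RPKM in low-performing pool 1 and 2927 RPKM in pool 2. ATP6, of the ATP synthase, had a log2 fold change of -0.17 ± 0.22 (SE), and ND3, the complex I subunit that did not pass, had one of -0.05 ± 0.29 (SE). As a set the list was lower by limma camera (adjusted p = 0.000247). The call was lost with an estimated correlation (adjusted p = 0.688) and without low-performing pool 1, where the median was -0.49; adjusted p ranged from 1.39e-11 to 0.688 over the alternatives. Without low-performing pool 2 the median was -0.98, and with the trend over gene length removed it was -1.0. ND4L overlaps ND4, ATP8 overlaps ATP6, and ND6 lies antisense to the end of ND5, and whether reads were counted by strand is not given in the sources used here, so these pairs are not fully separate measurements.

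**Figure D2:**
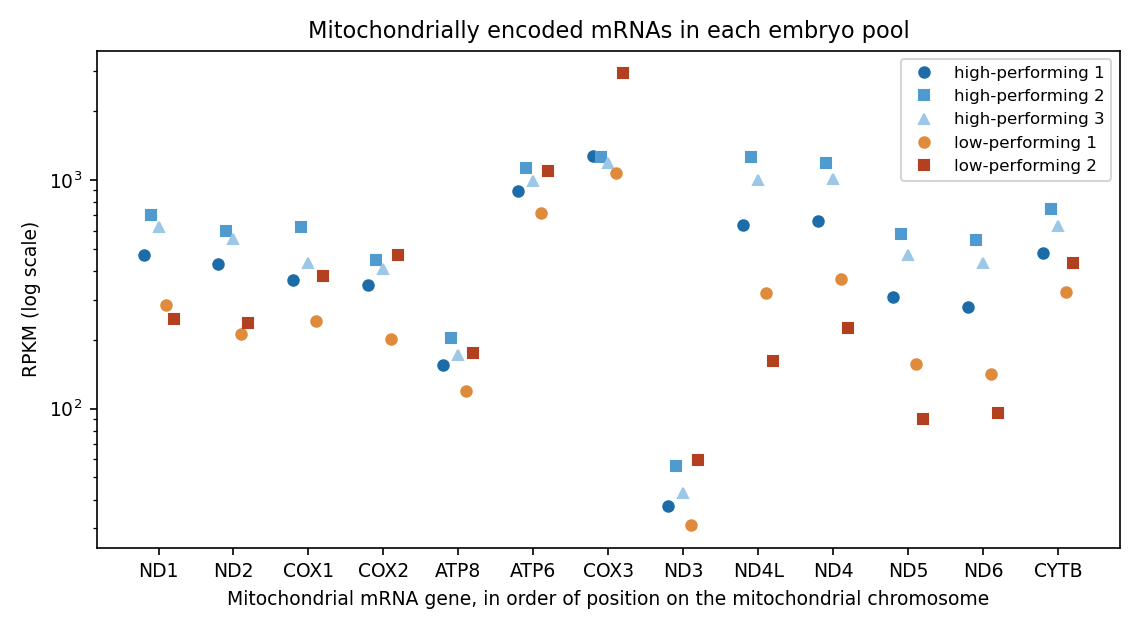
RPKM (log scale) of the 13 mitochondrially encoded mRNAs in each embryo pool, in order along the mitochondrial chromosome; each point is 1 pool. Both low-performing pools lie below all 3 high-performing pools for ND1, ND2, ND4L, ND4, ND5, ND6 and CYTB, while COX3 is highest in low-performing pool 2.

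Transcripts of the ubiquitin-proteasome system, which degrades proteins, had a median log2 fold change of 0.31 over 51 genes, with 19 risen and 3 fallen when p-values were adjusted over the list alone in limma. The risen members included the core proteasome subunit PSMB2, at 49.4 ± 8.66 RPKM (SD, n = 3) in the high-performing pools and 118 ± 44.4 RPKM (SD, n = 2) in the low-performing pools, and PSMB1, PSMA6 and PSMA7. PSME4, a proteasome activator, fell by 0.93 on the log2 scale. limma camera gave an adjusted p of 0.00068, and an adjusted p of 0.688 with an estimated correlation, within 0.00013 to 0.688 over the alternatives. The median was 0.19 without low-performing pool 2 and 0.12 with the length trend removed. Of 39 antioxidant genes tested, 13 rose and 1 fell with p-values adjusted over the list alone, around a median of 0.30. GLRX, the thiol reductase glutaredoxin, had 24.1 ± 9.44 RPKM (SD, n = 3) and 81.2 ± 30.3 RPKM (SD, n = 2), a log2 fold change of 1.72 ± 0.33 (SE), and superoxide dismutase SOD1 had 205 and 476 RPKM on average. TXNIP, an inhibitor of thioredoxin, fell by 0.60 on the log2 scale. The antioxidant list had an adjusted p of 0.0256 by limma camera and of 0.688 with an estimated correlation, within 0.0157 to 0.688 over the alternatives. This call also ended with a filter at a mean RPKM of at least 5, without low-performing pool 1 and with the length trend removed, where the median was 0.14. Of 12 sperm and spermatid markers above the filter, 2 rose with p-values adjusted over the list alone, the acrosomal protein gene ACRV1 and SPA17, around a list median of 0.26, which was 0.038 with no filter on low values and 0.44 with a mean RPKM of at least 5. ACRV1 had 5.80 ± 0.12 RPKM (SD, n = 3) and 12.8 ± 5.37 RPKM (SD, n = 2). The sperm list had an adjusted p of 0.0108 by limma camera and of 0.688 with an estimated correlation, within 0.00808 to 0.688 over the alternatives, and its call ended with the length trend removed, where the median was 0.040. PRM1, the sperm protamine, had 1 read in high-performing pool 1 and none in the other pools.

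Regulators of chromatin were lower in the low-performing pools. The 87 DNA methylation and chromatin modifiers had a median log2 fold change of -0.35, with 52 below every high-performing pool in both low-performing pools and 10 above. Chance gives 20% of genes in either direction on average over splits, and 58.7% of all genes tested did not overlap. None passed limma with p-values adjusted over the list alone or over all genes. CHD4, a nucleosome remodeller, had 30.9 ± 3.58 RPKM (SD, n = 3) and 17.8 ± 4.12 RPKM (SD, n = 2), a log2 fold change of -0.77 ± 0.18 (SE). The histone acetyltransferases EP300 and CREBBP had log2 fold changes of -1.2 ± 0.29 (SE) and -0.98 ± 0.24 (SE), while H3-3A, a gene for the replication-independent histone H3.3, stood at 0.81 ± 0.19 (SE). limma camera gave an adjusted p of 2.31e-06, and an adjusted p of 0.688 with an estimated correlation, within 1.32e-08 to 0.688 over the alternatives. The members are long, with a median of 4199 bases, and all genes tested of 4001 to 6000 bases had a median of -0.26. The list was not compared with random lists matched on length. The median was -0.15 without low-performing pool 2, -0.57 without pool 1 and -0.13 with the length trend removed.

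Genes of maternal mRNA storage and clearance, which hold or destroy the messages inherited from the egg, had a median log2 fold change of -0.35 over 44 genes, with none past limma adjusted over the list alone. CPEB4, which binds the 3' ends of stored mRNAs, had 27.2 ± 3.72 RPKM (SD, n = 3) and 12.2 ± 5.89 RPKM (SD, n = 2), a log2 fold change of -1.16 ± 0.27 (SE). CNOT6L, a deadenylase, stood at -1.06 ± 0.30 (SE). BTG4, which recruits that deadenylase complex to maternal mRNA, stood the other way at 0.90 ± 0.27 (SE), with 7710 ± 1668 RPKM (SD, n = 3) and 14380 ± 3625 RPKM (SD, n = 2). The list was lower by limma camera (adjusted p = 6.09e-05), with an adjusted p of 0.688 under an estimated correlation and a range of 4.29e-06 to 0.688 over the alternatives. Its median length was 3610 bases, and all genes tested of 3001 to 4000 bases had a median of -0.16. The list's median fold change was -0.20 without low-performing pool 2, -0.49 without pool 1 and -0.18 with the length trend removed. The 59 Wnt signalling genes had a median of -0.19, with none past limma adjusted over the list alone. NLK, a kinase that acts on the pathway's transcription factors, had 80.3 ± 14.2 RPKM (SD, n = 3) and 35.7 ± 20.0 RPKM (SD, n = 2), a log2 fold change of -1.25 ± 0.33 (SE). limma camera gave the Wnt list an adjusted p of 0.0059, and an adjusted p of 0.712 with an estimated correlation, within 0.00285 to 0.712 over the alternatives. That call ended without low-performing pool 2, where the median was -0.072, and with the length trend removed, where it was -0.050. Without low-performing pool 1 the median was -0.31. WNT5A itself was under the filter, at 0.34 to 0.79 RPKM in the 5 pools. The treatment protocol names recombinant Wnt5A for all 5 samples alike, so these Wnt values may not be those of untreated embryos.

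Oocyte-expressed maternal factors did not pass as a list, with a median log2 fold change of 0.14 over 34 genes (limma camera, adjusted p = 0.0809), and with quantile normalization their median was -0.10. With p-values adjusted over the list alone, 5 members rose, OOEP, OOSP2, NPM2, FIGLA and MOS, and 2 fell, DAZL and TLE6. OOEP, part of the egg's subcortical maternal complex, had 131 ± 23.3 RPKM (SD, n = 3) and 316 ± 142 RPKM (SD, n = 2), while TLE6, of the same complex, stood at -0.57 ± 0.16 (SE) on the log2 scale. BMP15 and GDF9, growth factors secreted by the oocyte, had log2 fold changes of 0.25 ± 0.18 (SE) and 0.22 ± 0.17 (SE), which turned to -0.16 and -0.05 with quantile normalization. RNA splicing factors had a median of 0.07 over 63 genes (limma camera, adjusted p = 0.148), with 18 risen and 4 fallen adjusted over the list alone. SF3B6, a subunit of the U2 particle, had 71.2 ± 20.1 RPKM (SD, n = 3) and 194 ± 61.2 RPKM (SD, n = 2), and SF3B2, of the same particle, stood at -1.07 ± 0.23 (SE). Pluripotency and lineage factors had a median of -0.20 over 22 genes (limma camera, adjusted p = 0.199). The median was -0.13 without low-performing pool 2, -0.33 without pool 1, -0.02 with no filter on low values and -0.34 with a mean RPKM of at least 5. KLF2 fell in the list alone, from 32.6 ± 5.87 RPKM (SD, n = 3) to 13.9 ± 6.58 RPKM (SD, n = 2), as did CDX2, the trophectoderm factor, while POU5F1 stood at 0.44 ± 0.15 (SE). Of 12 embryonic genome activation genes, with a median of -0.10 (limma camera, adjusted p = 0.642) that was -0.01 without low-performing pool 2 and -0.20 without pool 1, EIF1AX alone rose with p-values adjusted over the list alone, from 28.2 ± 1.81 RPKM (SD, n = 3) to 51.0 ± 13.4 RPKM (SD, n = 2). ZSCAN4 was under the filter, at 0.17 to 0.58 RPKM.

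The remaining lists did not pass limma camera, and none of their members passed when adjusted over the list alone. Median log2 fold changes were -0.04 for apoptosis, 0.01 for autophagy, -0.14 for cell cycle and mitosis, -0.14 for centrosome and centriole, -0.06 for cumulus and granulosa cell markers and -0.03 for DNA damage response and repair. They were -0.19 for glycolysis and pyruvate metabolism, -0.13 for heat shock and the unfolded protein response, -0.17 for imprinted genes, -0.07 for lipid and cholesterol metabolism and -0.009 for mitochondrial dynamics and biogenesis. Without low-performing pool 2 the median was -0.0024 for cell cycle and mitosis, -0.05 for centrosome and centriole and -0.03 for heat shock and the unfolded protein response, and it turned above 0 for apoptosis (0.01), DNA repair (0.02), lipid metabolism (0.03) and mitochondrial dynamics (0.009). Without low-performing pool 1 it was -0.21, -0.27 and -0.19 for the first 3 of these lists, -0.19 for apoptosis, -0.08 for DNA repair, -0.17 for lipid metabolism, -0.30 for imprinted genes and -0.04 for autophagy and for mitochondrial dynamics. For autophagy the mean and the test pointed down while the median lay above 0, for DNA repair the mean lay above 0 while the median and the test pointed down, and for mitochondrial dynamics the mean and the test pointed up. Members with the smallest p were VAMP8 at 0.51 ± 0.13 (SE), BAD at 0.79 ± 0.18 (SE), GMNN at 0.93 ± 0.22 (SE), AKAP9 at -1.04 ± 0.22 (SE), THBS1 at -0.80 ± 0.21 (SE) and ERCC5 at -0.57 ± 0.12 (SE). HK1 stood at 0.58 ± 0.16 (SE), HSPE1 at 0.91 ± 0.21 (SE), PHLDA2 at 0.85 ± 0.20 (SE), PMVK at 0.82 ± 0.20 (SE) and TOMM22 at 0.83 ± 0.19 (SE). The autophagy genes MAP1LC3B and SQSTM1 had log2 fold changes of 0.08 ± 0.13 (SE) and 0.25 ± 0.30 (SE), DNMT1 one of 0.18 ± 0.15 (SE) and PTX3 one of 0.06 ± 0.17 (SE). CCNB1, at 1282 ± 57.1 RPKM (SD, n = 3) and 1293 ± 6.02 RPKM (SD, n = 2), had a log2 fold change of 0.01 ± 0.15 (SE) that turned to -0.38 with quantile normalization. Cumulus and granulosa markers passed without low-performing pool 2, where their median was -0.18. Of the blood and immune markers only CD3E and CSF1R passed the filter, too few for a list test. Exact two-sided permutation tests of the list levels cannot give a p under 0.1 with 10 splits, and 14 of the 24 lists had levels that did not overlap between the groups.

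Gene by gene, the difference was widespread, and no single gene passed in the fit of the sire group alone on all 5 pools. limma gave 0 of 12448 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0829, and limma voom on the reads worked out from RPKM also gave 0. At an unadjusted p under 0.05 there were 4348 genes, 2367 higher and 1981 lower in the low-performing pools. The groups' libraries did not overlap for 58.7% of genes, against 20% by chance. That 20% is an average over the 10 splits of the pools into 3 and 2. Genes that vary together can lie far from it in a single split, so the excess does not measure a sire effect. The number at an unadjusted p under 0.05 was 2309 without high-performing pool 2, 2500 without high-performing pool 3, 6620 without low-performing pool 1 and 1808 without low-performing pool 2, of which 1251 were higher and 557 lower. At an adjusted p under 0.1 there were 2660 genes, 1669 higher and 991 lower, and with quantile normalization 1608 higher and 1557 lower. That number was 0 without high-performing pool 2, without high-performing pool 3, without low-performing pool 2, with no filter on low values and with the length trend removed. It was 1201 with library weights, 1486 without high-performing pool 1 and 6735 without low-performing pool 1. Without low-performing pool 1, so that pool 2 alone stood for its group and was assumed to vary like the high-performing pools, 5436 genes passed 0.05, and without any other pool 0 did.

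The named genes with the smallest p and no overlap between groups all had an adjusted p of 0.0829 in limma, which is not past 0.05. Among those higher in the low-performing pools were H4C9, a histone H4 gene on chromosome 23 (31355274 to 31355570), at 1.16 ± 0.19 RPKM (SD, n = 3) and 4.00 ± 0.59 RPKM (SD, n = 2), and SSR4, a translocon-associated protein of the endoplasmic reticulum, at 5.84 ± 0.41 RPKM (SD, n = 3) and 14.0 ± 3.60 RPKM (SD, n = 2). DCTN6, a subunit of the dynein activator dynactin, had 27.2 ± 3.85 RPKM (SD, n = 3) and 55.5 ± 6.05 RPKM (SD, n = 2). LAT2, NBDY, TMIGD1, DUSP29 and GAST stood at log2 fold changes of 0.85, 1.2, 0.83, 1.03 and 0.82. The short non-coding genes bta-mir-12054 and U1 stood at 0.97 and 0.79. Few reads lay behind bta-mir-12054, with 4 to 8 in the high-performing pools and 18 and 19 in the low-performing pools, and behind GAST, with 11 to 23 and 57 and 76. Lower in the low-performing pools were, besides the 6 mitochondrial complex I mRNAs, RESF1, a repressor of endogenous retroviruses, at 8.60 ± 0.93 RPKM (SD, n = 3) and 3.64 ± 1.12 RPKM (SD, n = 2), and RPP25, a subunit of the tRNA-processing enzyme RNase P, at 5.97 ± 0.53 RPKM (SD, n = 3) and 3.19 ± 0.10 RPKM (SD, n = 2). CLDN23 and bta-mir-2338 stood at -0.61 and -1.28.

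The authors' deposited table, from a likelihood ratio test, lists 2196 genes at an FDR under 0.05, 1520 higher and 676 lower in the low-performing group. Of these, 2006 were among the 12448 genes tested here, all 2006 had the same direction in limma and 1997 had an unadjusted p under 0.05. Ribosomal protein genes were higher 60 times and lower 0 times in the authors' deposited table, and oxidative phosphorylation genes higher 57 times and lower 0 times. There, 18 chromatin modifiers were lower and 2 higher, and 7 mitochondrially encoded mRNAs were lower. The gene with the smallest FDR in the authors' deposited table was TMSB4X, thymosin beta 4, which binds monomeric actin, with a log2 fold change of 1.66 (FDR = 3.02e-09). Its RPKM was 7080, 4854 and 4563 in the high-performing pools and 10478 and 24186 in the low-performing pools, where it took 0.88% and 2.04% of all reads in genes. The related TMSB10, the translocon subunit SEC61G and PTTG1, the inhibitor of separase, were also higher in the authors' deposited table, with log2 fold changes of 2.22, 1.94 and 1.45. SCD, a fatty acid desaturase, and CENPF, a kinetochore protein, were lower there, with -1.48 and -0.63. These genes were chosen after their values were seen.

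Gene length separated the pools as well. Across the genes tested, log2 fold change and gene length had a Spearman correlation of -0.52, where genes are not independent replicates. Genes of 501 to 1000 bases had a median log2 fold change of 0.50, and genes over 6000 bases one of -0.32. The trend lay in both low-performing pools and was steeper in pool 2, with medians of 0.32 and 0.69 for genes of 501 to 1000 bases relative to the high-performing mean, against 0.12, -0.07 and -0.05 in high-performing pools 1, 2 and 3. The first principal component held 84.1% of the variance and placed the pools at -28.8 and -24.1 (high-performing pools 2 and 3), -8.63 (high-performing pool 1), 9.07 (low-performing pool 1) and 52.4 (low-performing pool 2). The Pearson correlation across genes was highest between high-performing pool 1 and low-performing pool 1, at 0.99332. It was 0.99305 between high-performing pools 2 and 3, and 0.976 between the 2 low-performing pools. By the median chi-square of reads per gene, high-performing pools 2 and 3 were closest, at 7.41. That measure grows with depth, and these pools had the fewest reads. High-performing pool 1 was closer to low-performing pool 1, at 12.2, than to high-performing pools 2 and 3, at 13.9 and 13.6. Its Pearson correlations with high-performing pools 2 and 3 were 0.989 and 0.992, so the pools did not group fully by sire group.

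**Figure D3:**
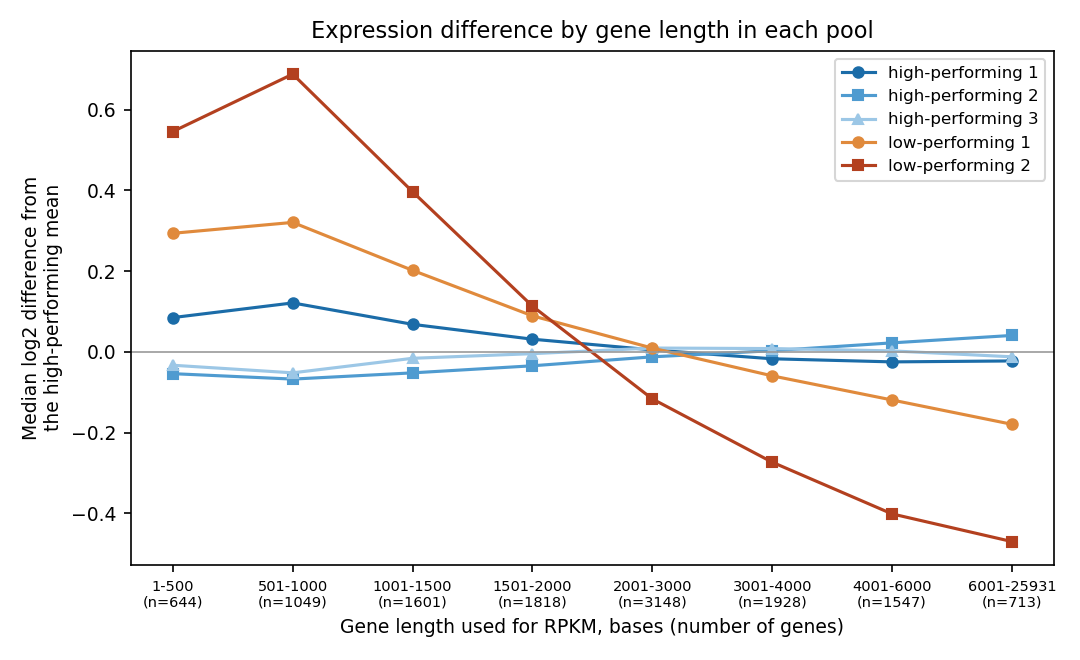
Median log2 difference from the mean of the high-performing pools, by gene length in bases, for each embryo pool; each line is 1 pool. In low-performing pool 2 the median goes from 0.69 for genes of 501 to 1000 bases to -0.47 for genes over 6000 bases, and in low-performing pool 1 from 0.32 to -0.18.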

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

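The removal of the length trend, limma voom, and the levels without a low-performing pool were chosen after the data were seen. Genes past an adjusted p of 0.05 in limma numbered 0 under both pseudocounts, both filters, quantile normalization, the trimmed-mean factor, limma without trend, with a robust prior or library weights, the length trend removed and voom. They numbered 2660 at a threshold of 0.1 (1669 higher, 991 lower) and 833 with the replicate number as a block (636 higher, 197 lower). Whether the numbers pair the pools is not given in the sources used here, and deviations of same-numbered pools, which correlate at -0.48 and -0.26, cannot settle it, since those of 2 low-performing pools mirror each other. High-performing pool 3 shares its number with no other pool and adds nothing to the blocked difference, so the like counts are those without it, 0 at 0.05 and 2500 at an unadjusted p under 0.05, where the block gave 2340 (4348 with all pools, 1808 to 6620 with a library left out). The block changed 1 list call, cumulus markers, which then passed. Leaving out a library gave 0 to 5436 genes, 0 to 2462 higher and 0 to 2974 lower, with 5436 only without low-performing pool 1, where 1 pool stands alone. The 9 list calls went to 0 with an estimated correlation and 0 with fry, and were 6 to 11 elsewhere (7 to 10 with a library left out). Lists newly past it were cumulus markers without low-performing pool 2 (median -0.18), oocyte factors without high-performing pool 1 (0.20), and centrosome and heat shock genes with no filter. Lists with levels apart numbered 14 in the main values and 14 to 21 elsewhere (17 to 21 without a low-performing pool). Named genes kept direction and side of the threshold in 789 combinations with an alternative, passed in 74 (the block, or without low-performing pool 1) and reversed in 11. The planned edgeR and DESeq2 tests on recovered reads were not run and voom was run on those reads instead, so the gap between 0 genes and the authors' 2196 was not examined with a count model.

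Reversals concern results that had not passed their test, and the cause was not tested. With a mean RPKM of at least 5 the test turned for autophagy (median 0.0070), DNA repair (0.014) and lipid metabolism (0.0078, level 0.019). With quantile normalization oocyte factors turned (-0.10), as did BMP15 (-0.16), CCNB1 (-0.38), GDF9 (-0.048) and the level of DNA repair (-0.013), and with the trimmed-mean factor the level of cell cycle (0.0050). CCNB1 turned with the replicate block (-0.0017) and without high-performing pools 2 (-0.0076) and 3 (-0.0017), and PTX3 without high-performing pool 2 (-0.045) and low-performing pool 2 (-0.028); with a library left out CCNB1 lay at -0.0076 to 0.050 and PTX3 at -0.045 to 0.19. The test turned for DNA repair without high-performing pool 1 (median -0.029, with a library left out -0.077 to 0.018) and for cumulus markers without low-performing pool 1 (median -0.077, with a library left out -0.18 to -0.044). With the length trend removed the test turned for autophagy (0.017), cell cycle (-0.014), DNA repair (0.099) and lipid metabolism (0.044), the levels of autophagy (0.0073), cell cycle (0.023), centrosome (4.1e-05) and lipid metabolism (0.069), and BMP15 (-0.045), PTX3 (-0.021) and CCNB1 (-0.16).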

Other observations

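The gene groups and tests of this part were chosen after the results were seen, except the count of splits. Messages for replication-dependent histones, the proteins that package newly copied DNA, were higher in the low-performing pools, with a median log2 fold change of 1.2 over 33 genes, 32 of them above 0. H2BC18 had 207 ± 50.5 RPKM (SD, n = 3) in the high-performing pools and 815 ± 591 RPKM (SD, n = 2) in the low-performing pools, and H4C1 had 50.1 ± 17.5 RPKM (SD, n = 3) and 219 ± 169 RPKM (SD, n = 2). None passed limma over all genes, while the authors' deposited table has 27 of the 33 higher and 1 lower at an FDR under 0.05. The list level was 3.05 to 3.41 in the high-performing pools, 3.66 in low-performing pool 1 and 4.89 in low-performing pool 2, and the median was 0.53 without pool 2. Reads shared among near-identical histone copies make single members uncertain.

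Core proteins of the spliceosomal snRNPs stood at a median log2 fold change of 1.43 over 8 genes, where SNRPE, SNRPF and SNRPG had 1.93, 1.86 and 1.93, and the authors' deposited table has 7 of the 8 higher. LSM proteins, their relatives in mRNA decay and splicing, had a median of 0.68 over 13 genes, and mitochondrial ribosomal proteins one of 0.67 over 75 genes, 72 of them above 0. By limma camera the unadjusted p was 1.64e-05 for the snRNP proteins, 0.00273 for the LSM proteins, 9.09e-17 for the mitochondrial ribosomal proteins and 4.68e-11 for the histones, and it lay between 0.169 and 0.232 for all 4 with an estimated correlation. Without low-performing pool 2 the medians were 0.89, 0.43 and 0.38 for snRNP, LSM and mitochondrial ribosomal proteins, and with the length trend removed they were 1.18, 0.25 and 0.46, and 0.66 for the histones. All 4 groups kept medians above 0 with quantile normalization and with the trimmed-mean factor.

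The higher ribosomal protein and nuclear oxidative phosphorylation mRNAs go with a trend over gene length, but that trend as the whole cause is argued against. The medians of 0.90 and 1.11 lay above the central 95% of 10000 random lists matched on length, 0.21 to 0.50 and 0.15 to 0.42. The random lists were drawn gene by gene, so these bands leave out variation that members share (estimated correlations of 0.72 and 0.74). Nor do they allow for the choice of these lists for the comparison after their values were seen. Length together with such shared differences between pools stays open. More cumulus or granulosa cells in the low-performing pools are argued against as well, since the upper quartile of their 28 tested markers was 0.030, under the lower quartiles of 0.65 and 0.57, and the most abundant markers STAR, SERPINE2, HAS2 and SPARC lay at -0.03 to -0.60, with LGALS1 at 1.13 as an exception. The sire group cannot be told apart from differences between single pools. The 2 low-performing pools differed by 0.79 in the ribosomal protein level, more than the 0.35 between the closest pools of the groups. Across genes, the contrast of low-performing pools 2 and 1 correlated with that of high-performing pools 1 and 2 (r = 0.41) and 1 and 3 (r = 0.47). It did not correlate with that of high-performing pools 3 and 2 (r = 0.009). The contrast of high-performing pools 1 and 2 also ran along the group difference. It correlated with low-performing pool 1 minus high-performing pool 3 (r = 0.65) and low-performing pool 2 minus high-performing pool 3 (r = 0.57). RNA integrity and the mix of stages between 2 and 4 cells may also differ between pools and were not tested.

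The lower mitochondrially encoded mRNAs go against the length trend, which would raise genes so short. Their median of -0.69 lay under the central 95% of random lists matched on length, -0.03 to 0.70. That band leaves out variation that members share (estimated correlation 0.43) and the choice of this list for the comparison after its values were seen. Whether a lower content of all mitochondrial transcripts is the whole cause is not settled. The log2 ratio of the 13 mRNAs to the mean of the 2 mitochondrial rRNAs differed by -0.94, with no overlap, which goes against it. That ratio was 0.55 ± 0.33 (SD, n = 3) in the high-performing pools and -0.39 ± 0.15 (SD, n = 2) in the low-performing pools. The rRNAs went opposite ways, however. The one of 955 bases stood at 0.39 ± 0.22 (SE), with 330 RPKM in low-performing pool 1 and 549 RPKM in pool 2 against 314 to 339 RPKM. The one of 1571 bases stood at -0.27 ± 0.13 (SE), lower in both low-performing pools than in all 3 others. Against it alone the ratio differed by -0.61, also with no overlap between the groups but within 2 SD of the high-performing pools (SD 0.34). A lower content as the whole or a part of the cause therefore stays open. Mitochondrial genes took 0.65%, 0.94% and 0.81% of reads in genes in high-performing pools 1, 2 and 3. Their share was 0.44% and 0.65% in low-performing pools 1 and 2. The log2 ratio of the 7 ND mRNAs to the other 6 was -0.60, -0.25 and -0.28 in the high-performing pools and -0.94 and -2.07 in the low-performing pools. Both low-performing pools thus lay under all 3 high-performing pools, which goes against a lower content alike for all mRNAs as the whole cause. The difference of -1.13 was within 2 SD of the low-performing pools (SD 0.80). That SD rests on 2 pools and is wide because pool 2 lies lowest, so it does not settle the question. The 2 low-performing pools differed in pattern, pool 1 lying under the high-performing pools in all 13 mRNAs and pool 2 in ND1, ND2, ND4, ND4L, ND5, ND6 and CYTB, while its 6 mRNAs other than ND had a level of 9.22 against 8.88 to 9.29 in the high-performing pools; a sire effect on mitochondrial RNA may be involved and was not tested apart from these pools.

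For the histones, a length trend as the whole cause is argued against, since the median of 1.2 lay above the central 95% of length-matched lists, 0.22 to 0.81. Length together with variation that members share (estimated correlation 0.77), which that band leaves out, is not excluded. The band also makes no allowance for the choice of this group after its values were seen. Carry-over of RNA without poly(A) tails, which these mRNAs typically lack, stays open. The 21 structural small RNAs tested had a median of 0.16 (quartiles -0.18 and 0.54), or -0.21 with the length trend removed. Most of them had low values, where a pseudocount of 1 understates a change, so that median cannot count against carry-over. Without low-performing pool 2 their median was 0.28, nearer to that of the histones, 0.53. Only 3 of the 21 had a mean RPKM of at least 10, too few to decide. Those 3, a 5S_rRNA, a U6 and a 7SK gene, stood at 0.52, 0.50 and 0.35, under the histone lower quartile of 0.87. The sire group was not tested apart from these pools.

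The 10 splits of the 5 pools into 3 and 2 are too few for a share under 0.05. The real split gave 4348 genes at an unadjusted p under 0.05, and no other split gave as many. The highest other split, high-performing pools 2 and 3 against the rest, gave 1973. Without high-performing pools 2 and 3 and low-performing pools 1 and 2 in turn, the number was 2309, 2500, 6620 and 1808.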
